A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

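The series measured RNA from Saccharomyces cerevisiae CEN.PK 113-7D, a laboratory yeast strain, on 16 Affymetrix GeneChip arrays with 9335 probe sets each. Per the labels' protocols, the cells grew aerobically under glucose limitation in a chemostat, a culture fed and drained at a constant rate, at a dilution rate of 0.05 per hour, pH 5 and 30 degrees C. A pulse then raised the residual glucose to about 1 g per litre (5.56 mM), and the labels say that cells were quenched in liquid nitrogen. Array titles gave the time point and the pulse number, which was used as the replicate number. The groups were the steady state before the pulse (3 arrays) and 30 s (2), 60 s (2), 120 s (3), 210 s (1), 300 s (3) and 330 s (2) after it. The labels state that each time point except 210 s came from at least 2 independent cultures.

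The authors deposited 1 signal per probe set and array, a linear intensity without a log, and GCOS, the Affymetrix software, is named in the submitters' processing notes. Its version and its settings are not given in the sources used here. The deposited intensity values were not on a common scale: the mean signal after trimming 2% at each end ran from 82.8 at 300 s replicate 3 to 325.9 at steady state replicate 2, a ratio of 3.94. No detection calls were used here, so the floor below stands in for a limit of detection. Experiment files of the arrays gave hybridization or scan days, which fell into 6 groups and were used only as a batch.

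Each array was rescaled to a trimmed mean of 150, signals under a floor of 12 (8% of that mean) were set to 12, and log2 was taken. Signals in the text are on this scale. Of the probe sets, 60 are controls, 6504 carry 1 gene in the platform annotation, 328 carry several and 2443 carry none in the annotation used here. All 6504 matched the RefSeq gene table of the R64 assembly, which served for names only, so no coordinates are given. For each of 5656 genes the probe set with the highest mean log2 signal was kept, and 246 genes above the floor on fewer than 2 arrays were left out, which left 5410 genes.

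One linear model was fitted to the 15 arrays of the 6 replicated time points with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a variance trend). It had 9 residual degrees of freedom and 6.3 from the prior. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05 per contrast. Errors of log2 fold changes are standard errors from this fit, and errors of signals are standard deviations. The 210 s array entered no test. The number of arrays limits the precision of every value.

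Before the data were examined, 24 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The rule named the 10 largest increases and 10 largest decreases at 120 s and 300 s, and 3 of each at 30 s, 60 s and 330 s and between 300 s and 120 s, among changed genes whose arrays at that time all lay on one side of all reference arrays. It added up to 4 changed members per list with the largest change at 300 s (where fewer than 2 had changed, the 2 members with the largest values), and 11 genes given whatever their test, PCK1, FBP1, ICL1, HXT1, HXT7, CLN3, MIG1, CAT8, ADE17, MET3 and HSP12. Lists were tested with camera, limma's test of a list against all other genes, with a preset correlation of 0.01 between members. Its p-values were adjusted over 144 tests, from 24 lists and 6 contrasts. Camera with an estimated correlation was run beside it. List medians are given relative to the median of all 5410 genes. The lists covered methionine and sulfur, purine and one-carbon, ribosome biogenesis, RNA polymerase I and III, single-copy ribosomal proteins, translation factors, glucose transport and sensing, glycolysis, gluconeogenesis and C2 metabolism, the TCA cycle, the respiratory chain, beta-oxidation, trehalose and glycogen, general stress, G1 cyclins, amino acid biosynthesis, nitrogen catabolite repression, phosphate, galactose and sucrose use, Ras and cAMP, mRNA decay, markers of both haploid mating types, and sporulation.

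The procedure was tested on simulated signals for the real genes, with 200 genes changed by known folds at 1 time point. Of genes changed 2-fold, 68.7% were recovered at 30 s, 82.1% at 60 s, 86.6% at 120 s, 84.8% at 300 s and 79.1% at 330 s. Of genes changed 1.5-fold, 26.9% were recovered at 30 s, 23.9% at 60 s and 37.3% at 120 s. Without any change, 0 genes were called over the 5 contrasts against steady state. In the runs with changed genes, 6 to 8 unchanged genes were also called. The simulated noise was independent between genes and arrays, so these rates do not cover effects shared by arrays of the same day or series. Alternatives covered the scaling, the floor, the filter on dim genes, the choice of probe sets, the variance model, blocks for pulse number, array-number series and hybridization day, each array left out, and stricter thresholds.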

Results

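Genome-wide transcript levels were measured in chemostat-grown yeast before a glucose pulse and at 6 times up to 330 s after it, on 16 arrays. The groups were the steady state (3 arrays), 30 s (2), 60 s (2), 120 s (3), 210 s (1), 300 s (3) and 330 s (2), and the trimmed mean signal of an array as deposited ran from 82.8 to 325.9. The question set by the design is how fast, and in which genes, transcript levels move when glucose-limited cells suddenly meet about 1 g of glucose per litre. Pairs of arrays of one time point differed by a median of 0.16 to 0.28 log2 units per gene, with correlations of log2 signals across genes of 0.967 to 0.989, so none were copies of each other. Steady-state pairs differed by 0.258 to 0.279 and 300 s pairs by 0.206 to 0.27. Pairs at 30 s, 60 s and 120 s differed less, by 0.157 to 0.196, while the fit shares 1 estimate of spread per gene over all time points. Between 1.65% and 4.86% of the 5410 tested genes lay at the floor on an array.

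Over the whole course, 1921 genes (35.5% of those tested) changed by limma's moderated F test. The change was concentrated late. No gene had changed by 30 s or 60 s, 4 had by 120 s, 1648 by 300 s and 2034 by 330 s, as the plot of called genes per comparison shows.

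**Figure D1:**
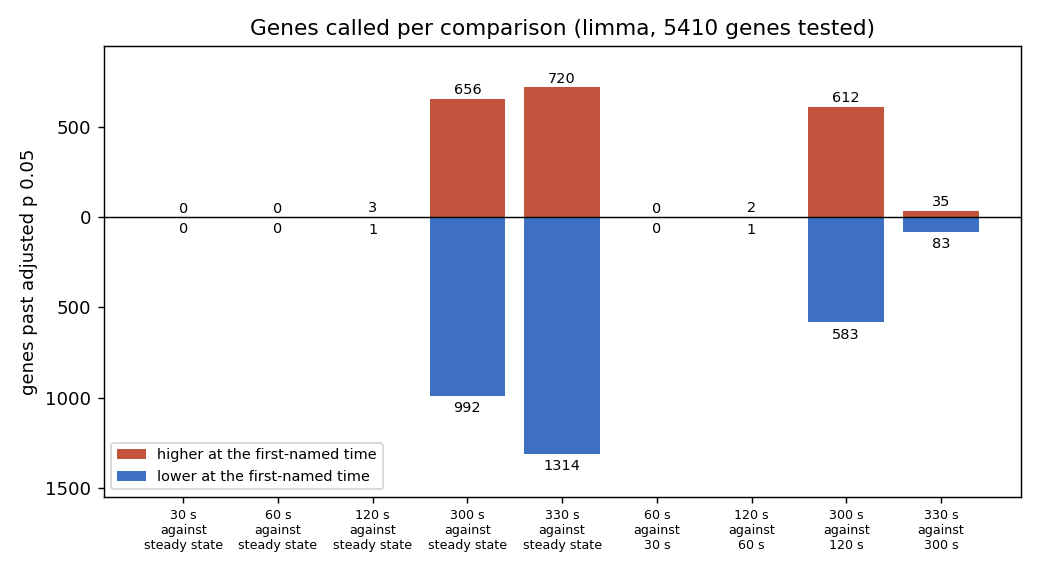
Genes past a limma adjusted p of 0.05 in each comparison (vertical axis, number of genes), with genes higher at the first-named time drawn upward and genes lower drawn downward. The count is 0 at 30 s and 60 s and 4 at 120 s, against 1648 at 300 s and 2034 at 330 s.

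During the first minute, no single gene was found to change beyond the spread of the arrays. Small changes could be missed, since 26.9% of simulated 1.5-fold changes were recovered at 30 s and 23.9% at 60 s. At 30 s, 0 genes passed limma's adjusted threshold and 336 had an unadjusted p under 0.05, where chance alone gives 270.5. At 60 s the numbers were 0 and 343, and between 60 s and 30 s they were 0 and 109. The 109 lies under the 270.5 of chance. The 30 s and 60 s arrays of the same replicate number share a hybridization day, which the main fit leaves out. Its shared estimate of spread also draws on time points whose arrays differed more. Whether either makes this contrast too strict was not tested, so its 0 is weak evidence of no change. Small shifts of whole groups were seen with camera's preset correlation. At 30 s the glycolysis list lay 0.20 log2 units above the median of all genes (limma's camera, adjusted p = 0.000423) and the purine and one-carbon list 0.14 above (adjusted p = 0.00547). The single-copy ribosomal proteins lay 0.11 above (adjusted p = 0.012) and the TCA cycle list 0.12 above (adjusted p = 0.0232). With an estimated correlation, the camera adjusted p of these 4 lists was 0.4, 0.4, 0.514 and 0.384. At 60 s the same 4 lists and the mRNA decay list were above the other genes, glycolysis by 0.19 (camera adjusted p = 0.000471 with the preset and 0.4 with an estimated correlation), and 0 of the 24 lists kept a call with an estimated correlation. Over all genes, 0 list members passed limma's threshold at either time, and adjusted over the list alone 1 amino acid biosynthesis gene was lower at 30 s and 0 members of the other lists passed. Dropping 30 s replicate 2 gave 17 genes at 30 s, and dropping 60 s replicate 2 or steady-state replicate 3 gave 3 and 2 genes at 60 s. Between 60 s and 30 s, 12 genes passed without 30 s replicate 2 and 3 without 60 s replicate 2.

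By 120 s, 3 genes had risen and 1 had fallen. MNC1 (YBR056W-A) rose 3.20-fold, from a signal of 127 ± 6.14 (SD, n = 3) to 408 ± 70.7 (SD, n = 3), a log2 change of 1.68 ± 0.20 (SE). ICY1 (YMR195W) rose by 1.11 ± 0.15 on the log2 scale and CPP2 (YDR210W) by 0.91 ± 0.13. The uncharacterised gene YMR206W fell from 655 ± 148 to 327 ± 28.1 (SD, n = 3 each), a log2 change of -0.98 ± 0.16. Their limma adjusted p-values were 0.00297, 0.00626, 0.00626 and 0.02. Between 60 s and 120 s, 3 of these 4 genes changed in the direct contrast, MNC1 by 1.60 ± 0.23, ICY1 by 1.08 ± 0.17 and YMR206W by -1.22 ± 0.18. That count was 7 without 60 s replicate 2, 1 without 120 s replicate 3, and 0 without 60 s replicate 3, 120 s replicate 1 or 120 s replicate 2.

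Among lists at 120 s, amino acid biosynthesis lay 0.17 log2 units above the median of all genes and the respiratory chain 0.15 above, with limma's camera adjusted p-values of 0.00159 and 0.00213. Single-copy ribosomal proteins, glycolysis and purine synthesis were also above the other genes (0.15, 0.16 and 0.14), and 0 members of these 5 lists had changed singly. With an estimated correlation their camera adjusted p was 0.137, 0.446, 0.467, 0.485 and 0.407. CLN3, a G1 cyclin that couples nutrients to division, had a signal of 66.9 ± 10.6 against 108 ± 33.9 at steady state (SD, n = 3 each), which did not pass (limma adjusted p = 0.415). The other genes given whatever their test did not pass either, with log2 values from -0.57 for HXT1 to 0.14 for ICL1. The 120 s count depends on single arrays, with 23 genes without steady-state replicate 3, 2 without steady-state replicate 1 or 120 s replicate 1, and 1 without 120 s replicate 2. Median centring of each array gave 3 up and 0 down, the array-number series as a block gave 10 genes and only the compared arrays in the fit 1. With hybridization day as a block the count was 0 (limma, 377 at an unadjusted p under 0.05, against 586 without the block), with log2 changes of 1.73 for MNC1, 1.08 for ICY1, 0.79 for CPP2 and -1.11 for YMR206W.

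At 300 s the largest increases were those of AQR1 and TPO2, both plasma membrane transporters. AQR1 (YNL065W) rose 23.8-fold (log2 4.57 ± 0.17 SE, n = 3 each), from a steady-state signal that was at the floor on 2 of 3 arrays, so that this fold understates the rise, to 306 ± 62.7 (SD). TPO2 (YGR138C), a polyamine exporter, rose 23.5-fold, from 34.1 ± 11.1 to 777 ± 132 (SD, n = 3 each). MAE1, the mitochondrial malic enzyme, rose 9.90-fold, PRM7 8.31-fold and VID24, a subunit of the ubiquitin ligase that marks gluconeogenic enzymes for destruction, 8.03-fold. DIA1, the riboflavin transporter MCH5, FSH1, YOR338W and MNC1 followed with increases of 7.87, 7.15, 6.31, 6.29 and 5.92-fold. The limma adjusted p of these 10 genes lay between 5.9e-11 and 2.01e-06.

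The largest decreases at 300 s were those of RGI1 and ISF1. ISF1 (YMR081C) fell 17.8-fold, from 599 ± 89.6 to 33.3 ± 1.65 (SD, n = 3 each), a log2 change of -4.16 ± 0.13 (SE) with a limma adjusted p of 1.26e-11. RGI1 (YER067W) fell from 348 ± 190 to 14.7 ± 4.69 (SD, n = 3 each), with 2 of its 3 arrays at the floor at 300 s, so its log2 change of -4.48 understates the fall. YMR206W fell 14.8-fold, YKR075C 13.8-fold and TMA10, which encodes a ribosome-associated protein, 11.6-fold. MPC3, a subunit of the mitochondrial pyruvate carrier, fell 8.54-fold, and HAP4, the regulatory subunit of the activator of respiratory genes, fell 7.86-fold, from 405 ± 67.4 to 51.1 ± 1.97 (SD, n = 3 each). YJR115W, RTC3 and RGI2 fell 7.01, 6.43 and 6.26-fold.

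**Figure D2:**
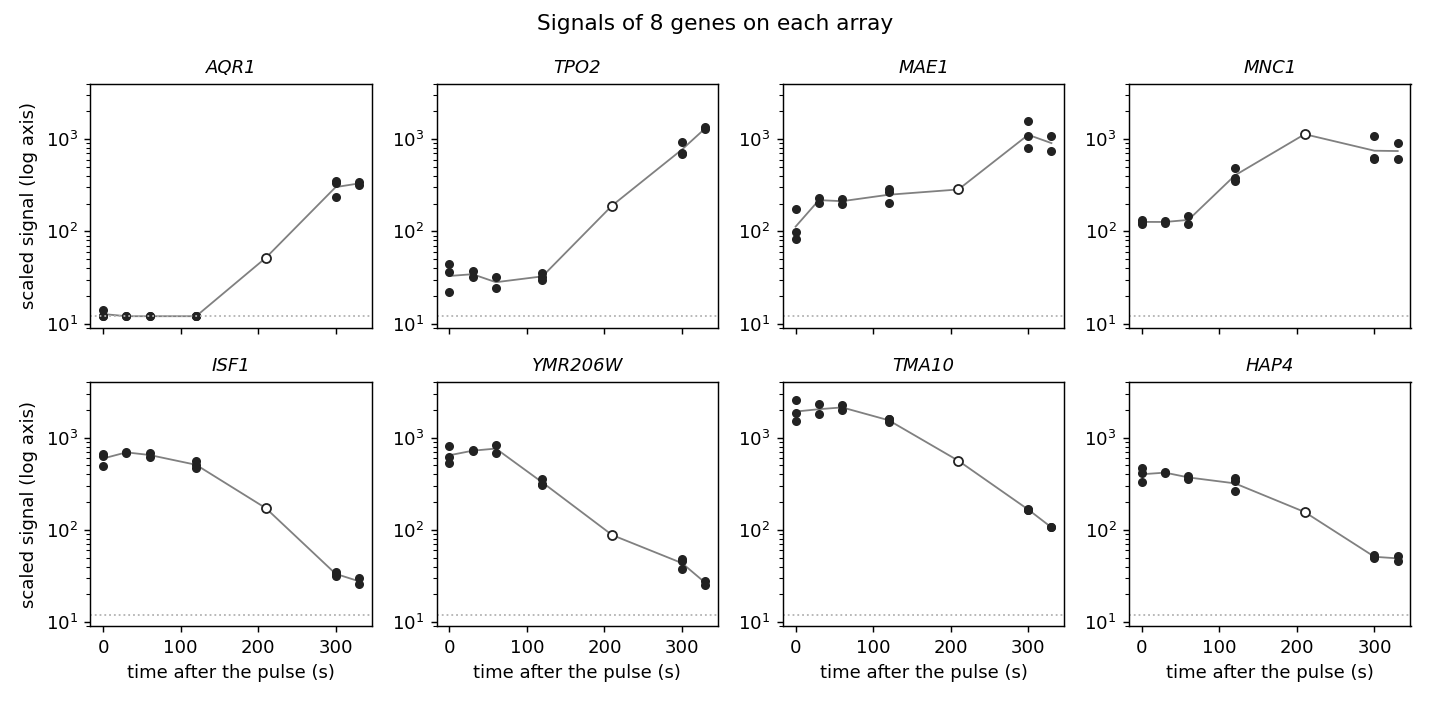
Scaled signal (log axis) against time after the pulse in seconds for 8 genes, with 1 filled point per array, an open point for the single 210 s array, a grey line through the mean log2 signal and a dotted line at the floor of 12. AQR1 and TPO2 stay near their steady-state level to 120 s and reach means of 306 and 777 at 300 s, while ISF1 and HAP4 reach means of 33.3 and 51.1.

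Genes for building ribosomes rose together at 300 s. Of 41 measured ribosome biogenesis genes, 31 rose and 0 fell (36 rose adjusted over the list alone), among them NOC4 by 1.62 ± 0.29, NOG2 by 1.60 ± 0.17, the nucleolin NSR1 by 1.46 ± 0.14 and the helicase DBP2 by 1.34 ± 0.18 on the log2 scale. The list median lay 0.91 above that of all genes (limma's camera, adjusted p = 1.89e-19, and adjusted p = 0.0426 with an estimated correlation). Of 20 subunits and factors of RNA polymerases I and III, which make ribosomal and transfer RNA, 8 rose (9 adjusted over the list alone), including RPA12 by 1.66 ± 0.21, RPC37 by 1.53 ± 0.18, RPC11 by 1.06 and RPA34 by 1.03. That list lay 0.64 above all genes (camera adjusted p = 4.9e-07, but adjusted p = 0.195 with an estimated correlation). Of 25 translation factors 7 rose (7 adjusted over the list alone), with GCD10 up 1.90-fold and RPG1 up 1.62-fold, followed by SUI3 and GCN3 with log2 changes of 0.59 ± 0.19 and 0.58 ± 0.14. The camera adjusted p was 3.23e-05, and 0.206 as an adjusted p with an estimated correlation. None of 19 single-copy ribosomal protein genes passed singly, over all genes or adjusted over the list alone. RPL39 had a log2 value of 0.79 ± 0.31 (SE) and RPL5 of 0.37 ± 0.15. Their list lay 0.34 above all genes (camera adjusted p = 0.00653), a call that was lost with an estimated correlation (adjusted p = 0.476) with quantile normalization (adjusted p = 0.433) and without steady-state replicate 2 (list median 0.21 above all genes).

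Biosynthetic genes for purines and amino acids also rose. Of 22 purine and one-carbon genes, 18 rose and 0 fell (20 adjusted over the list alone), with the IMP dehydrogenase IMD4 up 3.67-fold (log2 1.88 ± 0.18 SE, n = 3 each), MTD1 3.34-fold, ADE1 3.03-fold, ADE2 2.96-fold and ADE17 2.05-fold. Their median lay 1.11 log2 units above all genes (limma's camera, adjusted p = 1.86e-14, and adjusted p = 0.0405 with an estimated correlation). Among 30 amino acid biosynthesis genes 17 rose and 1, TRP4, fell (18 and 1 adjusted over the list alone). LYS20, the first enzyme of lysine synthesis, rose 2.37-fold, HIS3 2.09-fold, LYS1 1.89-fold and HIS1 1.81-fold (camera adjusted p = 8.03e-09, and adjusted p = 0.0405 with an estimated correlation). Of 25 methionine and sulfur genes 14 rose and 2 fell (16 and 2 adjusted over the list alone). The permease MUP3 rose 3.48-fold, MET8 2.35-fold, the S-adenosylmethionine synthetase SAM1 2.26-fold, STR3 1.93-fold and MET3 1.39-fold. Both that fell, MMP1 and MHT1, take up and use S-methylmethionine, with log2 changes of -0.86 and -0.57, and were named after their values were seen. This list lay 0.60 above all genes (camera adjusted p = 1.68e-05, but adjusted p = 0.0689 with an estimated correlation).

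Reserve carbohydrate and fatty acid oxidation genes fell at 300 s. Of 17 trehalose and glycogen genes 13 fell and 0 rose (13 adjusted over the list alone). The glycogen branching enzyme GLC3 fell 4.09-fold (log2 -2.03 ± 0.16 SE, n = 3 each), the glycogenin GLG1 3.99-fold, the trehalose synthase subunit TSL1 3.22-fold and GAC1, which directs a phosphatase to glycogen synthase, 3.13-fold. The list lay at -0.78 relative to all genes (limma's camera, adjusted p = 3.18e-07, but adjusted p = 0.0518 with an estimated correlation). Of 14 beta-oxidation and peroxisome genes 12 fell (13 adjusted over the list alone), led by the fatty acyl transporter subunit PXA1, down 3.18-fold, the acyl-CoA oxidase POX1, down 2.84-fold, PXA2, down 2.19-fold, and ECI1, down 1.89-fold. Its camera adjusted p was 6.03e-06, and the adjusted p with an estimated correlation was 0.0405. Of 19 gluconeogenesis and C2 genes 13 fell (14 adjusted over the list alone), with the mitochondrial carriers CRC1 and SFC1 down 2.16-fold and 2.13-fold, CAT2 down 1.84-fold, MLS1 down 1.79-fold and the activator CAT8 down 1.72-fold (camera adjusted p = 8.14e-05, but adjusted p = 0.195 with an estimated correlation). FBP1, fructose-1,6-bisphosphatase, fell by 0.59 ± 0.19 on the log2 scale, with limma adjusted p = 0.0287 and 0.0576 after quantile normalization. PCK1 and ICL1, the key enzymes of gluconeogenesis and the glyoxylate cycle, did not pass, with log2 values of -0.33 ± 0.15 and -0.38 ± 0.14 (SE, n = 3 each, limma adjusted p = 0.12 and 0.0515).

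Genes for glucose uptake, phosphorylation and sensing moved mostly down. Of 20 measured, 10 fell and 1 rose (11 and 1 adjusted over the list alone). MTH1, a repressor of hexose transporter genes, fell 5.76-fold (log2 -2.53 ± 0.17 SE, n = 3 each). The hexokinase HXK1 fell 2.35-fold, the glucose repressor MIG1 2.27-fold and its relative MIG2 2.89-fold, which understates the fall since 2 of 3 arrays were at the floor at 300 s. The one that rose was STD1, a relative of MTH1, by 1.12 on the log2 scale, named after its value was seen. The low-affinity transporter gene HXT1 had a log2 value of 0.07 ± 0.22 and HXT7, whose probe set may also bind its near-identical neighbour HXT6, of -0.25 ± 0.17 (limma adjusted p = 0.835 and 0.286). With quantile normalization HXT7 passed, at -0.44 (limma adjusted p = 0.00493). This list lay at -0.38 relative to all genes (camera adjusted p = 0.00989, but adjusted p = 0.206 with an estimated correlation).

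Members of the glycolysis, TCA cycle and respiratory chain lists that passed changed by under 2-fold. Of 16 glycolysis and ethanol genes 4 rose (4 adjusted over the list alone), PDC6 by 1.87-fold, PDC1 by 1.42-fold, CDC19 by 1.39-fold and PFK1 by 1.26-fold. Their call (limma's camera, adjusted p = 0.00386) was lost with an estimated correlation (adjusted p = 0.453) and with quantile normalization (adjusted p = 0.225). Of 17 TCA cycle genes 6 fell and 1 rose (7 and 1 adjusted over the list alone). The malate dehydrogenase MDH1 fell 1.93-fold, KGD2 1.51-fold and CIT3 1.45-fold, and PYC1, a pyruvate carboxylase that feeds the cycle, rose 1.51-fold (camera adjusted p = 0.0413, but adjusted p = 0.407 with an estimated correlation). The TCA cycle call was also lost with median centring and without steady-state replicate 3 or 300 s replicate 2. Of 28 respiratory chain and ATP synthase genes 3 fell, NDI1, CYT1 and NDE1 by 0.53, 0.46 and 0.44 as log2 changes (3 adjusted over the list alone). That list was not called (camera adjusted p = 0.845), and its median lay 0.08 above all genes although the test leaned down.

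**Figure D3:**
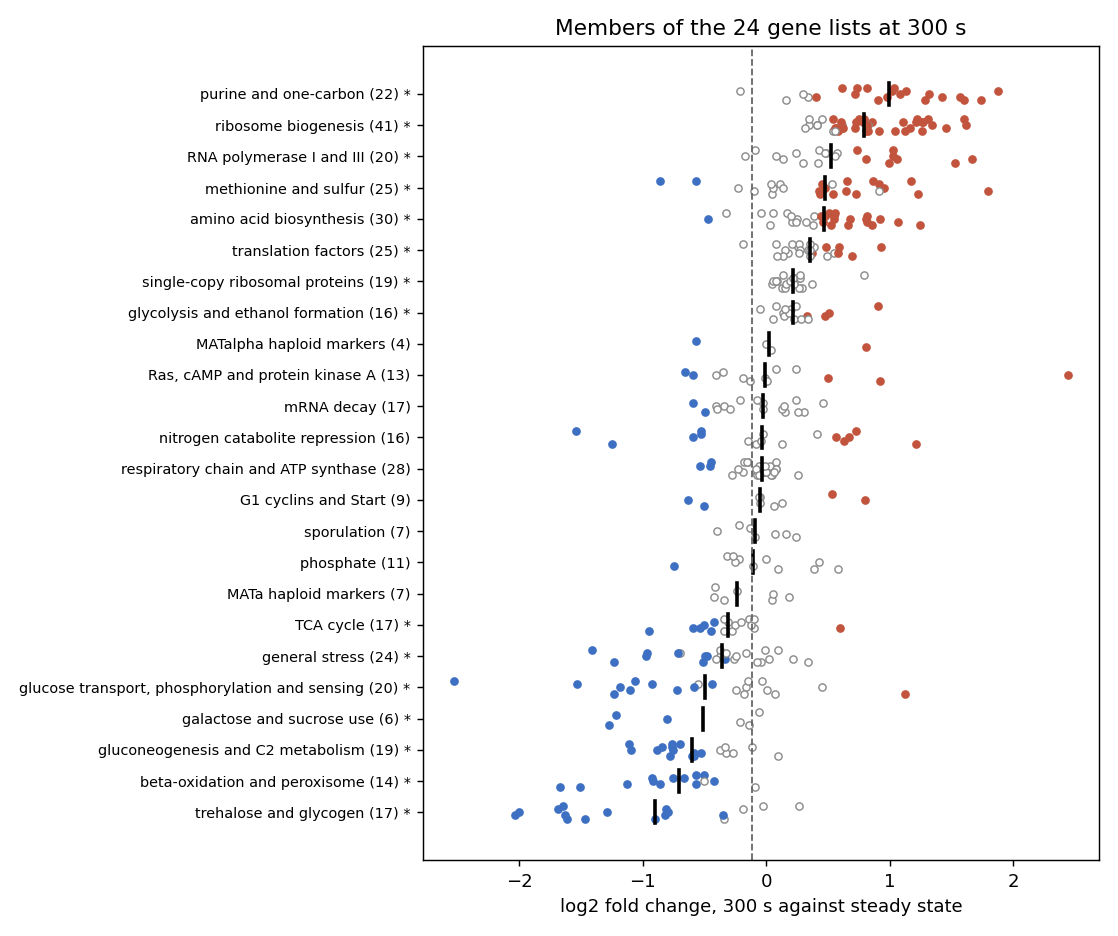
Log2 fold change at 300 s against steady state (horizontal axis) of each member of the 24 lists (vertical axis, with the number measured), filled where the gene passed limma's adjusted p of 0.05, red above 0 and blue below. Black bars are list medians, the dashed line is the median of all genes (-0.12), and stars mark the 15 lists called by camera with the preset correlation, of which single-copy ribosomal proteins, glycolysis and galactose and sucrose use are not called after quantile normalization. With an estimated correlation 4 lists are called.

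Of 24 general stress genes 9 fell and 0 rose (11 and 1 adjusted over the list alone), with the repressor XBP1 down 2.65-fold, RTN2 2.35-fold, GRE3 1.96-fold and DCS2 1.95-fold (limma's camera, adjusted p = 0.033, but adjusted p = 0.541 with an estimated correlation). The general stress call was also lost without steady-state replicate 1 or 300 s replicate 1. HSP12, a small heat-shock protein gene, had a log2 value of -0.04 ± 0.18 (SE) at 300 s and 0.07 ± 0.20 at 330 s, and passed at neither time. Of 6 galactose and sucrose genes 3 fell (3 adjusted over the list alone), the invertase SUC2 2.41-fold, GAL4 2.33-fold and GAL3 1.75-fold, with a camera adjusted p of 0.0494 that was lost in 17 of 31 alternatives, among them those without steady-state replicate 2 or 3 or without 300 s replicate 2, and with an estimated correlation (adjusted p = 0.463).

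Several lists without a call held members that moved apart. In the Ras, cAMP and protein kinase A list, PDE2, the high-affinity cAMP phosphodiesterase, rose 5.43-fold, from 66.3 ± 17.4 to 352 ± 42.9 (SD, n = 3 each), and RAS1 rose 1.89-fold, while TPK2 and CDC25 fell 1.58-fold and 1.51-fold. In all, 3 of its 13 members rose and 2 fell. Of 16 genes under nitrogen catabolite repression 5 rose and 5 fell, with the proline permease PUT4 down 2.91-fold, the arginase CAR1 down 2.37-fold, the glutamine synthetase GLN1 up 2.32-fold and DAL2 up 1.65-fold. Of 9 G1 genes CLN3 rose 1.74-fold and PCL1 1.45-fold, while SWI6 fell 1.55-fold and CLN1 1.42-fold. CLN3 did not pass with hybridization day as a block (log2 0.44, limma adjusted p = 0.217). Adjusted over the list alone, the counts of these 3 lists were the same: 3 up and 2 down, 5 up and 5 down, and 2 up and 2 down. In the phosphate list PHO8 fell 1.67-fold (1 adjusted over the list alone), while PHO4 and PHO89 had log2 values of 0.58 ± 0.27 and 0.42 ± 0.29. In the mRNA decay list DCP2 fell 1.51-fold and LSM1 1.41-fold (1 adjusted over the list alone).

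As markers of mating type and meiosis, the MATa list had 0 of 7 members changed, with log2 values of -0.42 ± 0.32 for ASG7 and -0.41 ± 0.24 for BAR1. The MATalpha list had 1 of 4 up, the pheromone gene MF(ALPHA)1, 1.75-fold, and 1 down, SAG1, 1.48-fold (1 and 1 adjusted over the list alone). The sporulation list had 0 of 7 changed, with IME1 at -0.40 ± 0.28 and DIT1, at the floor on all 3 steady-state arrays, at 0.24 ± 0.16. The camera adjusted p of the 9 uncalled lists lay between 0.475 and 0.987.

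Of the 1648 genes changed at 300 s, 656 rose and 992 fell, and 209 rose and 189 fell at least 2-fold. The median gene lay at -0.12 under the trimmed-mean scaling and at -0.01 under median centring, and the split moved with the scaling. Quantile normalization gave 779 up and 768 down, median centring 824 up and 687 down, and values as deposited 15 up and 36 down. With only the arrays of both time points in the fit, 938 genes passed, 436 up and 502 down. On the day shared by steady state replicate 3 and 300 s replicate 3, 99.4% of the 352 genes called higher without that day's arrays were higher, and 94.6% of the 501 called lower were lower. On the day shared by steady state replicate 2 and 300 s replicate 1, the shares were 90.9% of 639 and 95.2% of 853. With day as a block 1586 genes passed, and limma's camera no longer called the TCA cycle (adjusted p = 0.0726) or general stress (adjusted p = 0.0705). The experiment entry of 300 s replicate 1 names a culture with benzoic acid, unlike its label, and without that array 1705 genes passed.

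Each of the 15 called lists lay on the same side of all genes within both of those days. The lists were called from a fit that held these same arrays, so this agreement is partly built in. With an estimated correlation, camera called 4 lists at 300 s. Relative to all genes, ribosome biogenesis lay at 0.97 and 0.79 within the days of replicate 3 and replicate 1 at 300 s, and at 0.83 with day as a block. In the same order, purine and one-carbon genes lay at 1.10, 0.93 and 1.00, methionine and sulfur at 0.75, 0.50 and 0.60, amino acid biosynthesis at 0.56, 0.51 and 0.60, and RNA polymerases I and III at 0.68, 0.44 and 0.47. Translation factors lay at 0.45, 0.30 and 0.38, glycolysis at 0.29, 0.39 and 0.36, and single-copy ribosomal proteins at 0.24, 0.34 and 0.31. Trehalose and glycogen lay at -0.73, -0.81 and -0.64, beta-oxidation at -0.70, -0.46 and -0.63, gluconeogenesis at -0.50, -0.27 and -0.46, and glucose transport at -0.35, -0.31 and -0.32. Galactose and sucrose use lay at -0.53, -0.55 and -0.41, general stress at -0.15, -0.26 and -0.15, and the TCA cycle at -0.25, -0.06 and -0.09.

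Between 120 s and 300 s, 612 genes rose and 583 fell in the direct contrast. AQR1, at the floor on all 3 arrays at 120 s, rose at least 25.2-fold, TPO2 rose 23.7-fold and PRM7 9.46-fold. ISF1 fell 15.2-fold, from 509 ± 46.1 to 33.3 ± 1.65 (SD, n = 3 each), YKR075C 9.47-fold and TMA10 9.31-fold. CLN3 rose 2.71-fold (log2 1.44 ± 0.26 SE, limma adjusted p = 8e-04), MIG1 fell 2.14-fold, CAT8 1.78-fold and ICL1 1.43-fold, while ADE17 rose 2.14-fold and MET3 1.33-fold. PCK1, FBP1, HXT1, HXT7 and HSP12 did not pass, with log2 values of -0.41, -0.41, 0.64, -0.23 and -0.12, although HXT7 passed with quantile normalization (-0.34, limma adjusted p = 0.0267). In the lists, 33 of 41 ribosome biogenesis genes and 19 of 22 purine and one-carbon genes rose (35 and 19 adjusted over the list alone), and 12 of 17 trehalose and glycogen genes and 11 of 14 beta-oxidation genes fell (14 and 13 adjusted over the list alone). Limma's camera called 13 of the 24 lists, 6 up and 7 down, and 5 with an estimated correlation. The blocked count with hybridization day was 1298 genes, and values as deposited gave 36. Which side was larger depended on the processing, with 723 up and 821 down with the array-number series as a block and 667 up and 514 down with median centring.

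The single 210 s array, which has no replicate check, showed part of this change. The 612 genes that rose had a median log2 difference from 120 s of 0.20 at 210 s against 0.85 at 300 s, and 75.7% were above their 120 s mean. The 583 genes that fell had a median of -0.24 at 210 s against -0.68 at 300 s, and 86.1% were below. Both differences share the 120 s arrays, and in 100 simulations with no change between 120 s and 210 s the median shares were 56.5% above and 58.5% below, the highest 61% and 62.7%, and the medians 0.04 and -0.05. AQR1 read 51.7 at 210 s and TPO2 190, while ISF1 read 172 and HAP4 156. MNC1 read 1130 at 210 s, against 408 at 120 s and 778 at 300 s, and DIA1 read 1470 against 294 and 947.

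At 330 s TPO2 had risen 39.9-fold, from 34.1 ± 11.1 (SD, n = 3) to 1310 ± 45.2 (SD, n = 2), AQR1 26.1-fold, understated since 2 of 3 steady-state arrays were at the floor, and DIA1 by a log2 change of 3.33 ± 0.31 (SE). RGI1, at the floor on both arrays, had fallen at least 26.5-fold, YMR206W 24.1-fold and ISF1 21.5-fold. MIG1 had fallen 3.48-fold, FBP1 2.40-fold, CAT8 2.21-fold and ICL1 1.34-fold, while ADE17 had risen 2.47-fold and MET3 1.65-fold. PCK1, HXT7, HXT1 and CLN3 did not pass, with log2 values of -0.09 ± 0.17, -0.29 ± 0.19, -0.33 ± 0.25 and 0.43 ± 0.29 (limma adjusted p = 0.702, 0.248, 0.312 and 0.259), although HXT7 passed with quantile normalization (-0.56, limma adjusted p = 0.00154). Of 41 ribosome biogenesis genes 37 rose (37 adjusted over the list alone), and of 17 trehalose and glycogen genes 14 fell (16 down and 1 up adjusted over the list alone). Limma's camera called 14 lists, 8 up and 6 down, of which 6 held with an estimated correlation.

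In all 720 genes rose and 1314 fell at 330 s, with a median gene at -0.19 under the trimmed-mean scaling and -0.04 under median centring, where 936 rose and 892 fell. Quantile normalization gave 848 up and 1120 down, and values as deposited 11 up and 106 down. With only the compared arrays in the fit 1299 passed, 493 up and 806 down. Without 330 s replicate 1 the total was 1335. Both 330 s arrays and steady state replicate 1 carry the lowest array numbers and had the highest 3' to 5' ratios of the actin control, a measure of RNA and labelling quality. The ratio was 3.99 ± 0.57 (SD, n = 3) on these and 2.39 ± 0.22 (SD, n = 13) on the other arrays (two-sided exact permutation p = 0.00179, the smallest that 560 splits allow, 0.0107 after adjustment over 6 tests). At 330 s it was 4.30 ± 0.32 (n = 2) against 2.67 ± 0.63 at steady state (n = 3, two-sided exact permutation p = 0.2, where 0.1 is the smallest possible). At 300 s it was 2.42 ± 0.11 (n = 3, two-sided exact permutation p = 1). Only this last comparison was planned. For the TATA-binding protein control the ratio was 4.48 ± 1.20 (SD) on the low-numbered arrays and 3.35 ± 0.33 on the others (two-sided exact permutation p = 0.0107, 0.0321 after adjustment). There the series was not uniformly highest, with 3.99 at 60 s replicate 3 against 3.88 at 330 s replicate 2. Both 330 s arrays were hybridized on a day that held no other time point, so day and time cannot be told apart for this comparison.

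Compared directly with 300 s, 35 genes were higher and 83 lower at 330 s, and with median centring 44 were higher and 39 lower. The glycogen gene GAC1 differed by -1.52 ± 0.30 (SE) on the log2 scale (limma adjusted p = 0.0197) and the vacuolar lipase ATG15 by -2.29 ± 0.34 (limma adjusted p = 0.00692), both named after their values were seen. The count was 246 without steady-state replicate 1, 1 and 19 without 330 s replicate 1 and 2, 21 and 65 without 300 s replicate 3 and 1, 61 without 60 s replicate 2 or 3, 62 without 120 s replicate 1 and 76 without 120 s replicate 2 or 3. It was 1 with only the compared arrays in the fit and 388 with all probe sets. By limma it was 0 with the array-number series as a block (587 at an unadjusted p under 0.05, against 1064 without it), where the median SE rose from 0.20 to 0.30 because 1 steady-state array alone ties the 330 s arrays to the others, and it stands beside the higher 3' to 5' ratios of the 330 s arrays.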

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

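All tests below were fixed before their result was seen, except that of whether 300 s replicate 1 came from a culture without a pulse and the simulation of no change after 300 s, which were chosen after the result was seen. The weak-acid genes used in the benzoic acid test, however, are a gene family that was chosen after other results had been seen.

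Between 330 s and 300 s, 118 genes differed by limma's direct contrast, 35 higher and 83 lower at 330 s (44 and 39 with median centring), which marks a difference between time points under the same contrast. Across the 118 genes, the difference correlated with that between steady state replicate 1, an array of the same low-numbered series as the 330 s arrays, and the other steady-state arrays, with r = 0.74 (95% bootstrap interval 0.61 to 0.82, across genes, which are not independent). A response still running at 300 s also met its test, since 75.4% of the genes (exact 95% interval 66.6 to 82.9) differed in the direction of their change from 120 s to 300 s. Both differences share the 300 s arrays, and simulated signals with the observed change to 300 s and none after gave a median of 31.4% (19.5% to 42.4% in 100 simulations) over the 118 genes with the smallest p. Neither explanation is excluded, so the difference may be technical, biological or both, and the array series as a block does not decide, since it left 0 genes past limma's threshold (587 at an unadjusted p under 0.05, against 1064 without it) but ties the 330 s arrays to the others through 1 steady-state array and raised the median SE from 0.20 to 0.30, with the median size of the 118 differences at 0.63 against 0.82 and all 118 in the same direction.

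The experiment entry of 300 s replicate 1 names a culture with benzoic acid, while its label gives the glucose pulse. An array of a culture that got no pulse is argued against by the slope of its change from steady state on the change of the other 300 s arrays from 120 s, 0.85 (95% bootstrap interval 0.82 to 0.88 over 492 genes called at 2-fold or more without it), where no pulse would give a slope near 0. A culture grown with benzoic acid is argued against by 6 genes induced by weak acids, whose median on this array lay at -0.19 relative to the other 300 s arrays (from -0.63 to 0.13 over the 6 markers), where a median over 1 log2 unit was set as the mark. What the entry refers to was not tested further.

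Among probe sets outside the comparisons, 112 of 1334 measured probe sets (8.4%) that carry no gene in the annotation passed limma's threshold at 300 s, 20 higher and 92 lower. Of 292 measured probe sets that carry several genes, 33 (11.3%) passed, 10 higher and 23 lower, and at 30 s 0 of either kind passed. Both shares lie under that of the tested genes, of which 1648 of 5410 passed at 300 s in the main fit. These directions were taken under the trimmed-mean scaling alone.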

How the results depend on the processing

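Of these alternatives, leaving out both arrays of the shared day of 300 s replicate 1, array brightness as a covariate and day as a random block were chosen after seeing the data, and the others before. No named gene or list at 300 s reversed where the main or the alternative value passed. The balance of higher and lower genes turned with median centring, to 824 and 687 at 300 s, 936 and 892 at 330 s and 44 and 39 between 330 s and 300 s. This balance turned in other settings too, at 300 s with quantile normalization (779 and 768). Between 300 s and 120 s, from 612 and 583, it turned with blocks for array-number series (723 and 821) and pulse number (690 and 750), among others. The cause was not tested where a value moved, except where fewer arrays or a stricter threshold set it. With values as deposited, 106 genes passed the F test, 0 at 120 s, 51 at 300 s, 117 at 330 s, 0 between 120 s and 60 s, 36 between 300 s and 120 s and 0 between 330 s and 300 s (limma). Without the filter on dim genes 1 gene passed at 60 s, 1 between 60 s and 30 s and 1 between 120 s and 60 s, and with all probe sets 388 passed between 330 s and 300 s. With only the compared arrays in the fit, 1 gene passed at 120 s, 938 at 300 s, 1299 at 330 s, 0 between 120 s and 60 s and 1 between 330 s and 300 s. At least 2-fold, 2 genes passed at 120 s, 398 at 300 s, 689 at 330 s, 332 between 300 s and 120 s and 32 between 330 s and 300 s. At an adjusted p under 0.01 there were 952 at 300 s, 1283 at 330 s, 0 between 120 s and 60 s, 713 between 300 s and 120 s and 12 between 330 s and 300 s. The array-number series as a block gave 10 genes at 120 s, 5 between 120 s and 60 s and 0 between 330 s and 300 s, and hybridization day as a block 0 at 120 s. Without both arrays of the shared day 1 gene passed at 120 s and 60 between 330 s and 300 s, where brightness as a covariate gave 272 and day as a random block 34. Leaving out each array in turn gave 1400 to 2120 genes by the F test, 0 to 17 at 30 s, 0 to 3 at 60 s, 1 to 23 at 120 s, 1229 to 1705 at 300 s, 1335 to 2103 at 330 s, 0 to 12 between 60 s and 30 s, 0 to 7 between 120 s and 60 s, 892 to 1271 between 300 s and 120 s and 1 to 246 between 330 s and 300 s, where a lone array left at a time point is assumed to vary like the others. Pulse number was not taken to pair the arrays, since not every pair with the same number correlated over 0.1, a rule that cannot exclude pairing. Deviations from the group means correlated at a median of 0.15 over 31 pairs with the same number (-0.2 to 0.42, 20 over 0.1) and of -0.09 over 62 pairs with different numbers (7 over 0.1), which leaves a shared culture open. Such deviations cancel within a time point, so positive values for same-numbered pairs push those for different numbers down. Of the same-numbered pairs, the 15 hybridized on different days had a median of 0.09 (7 over 0.1). As a replicate block the number gave 2148 genes by the F test, 13 at 120 s and 1932 at 300 s, and as a random replicate block 210 between 330 s and 300 s. Of 5436 alternative values of named genes 5124 stayed on their side of the threshold, 247 no longer passed and 65 passed newly. Of 812 list values 767 stayed on their side and 45 no longer passed. A change of direction was counted only where the main or the alternative value passed, so values that passed in neither may have changed sign. All these list values are for 300 s against steady state. List calls of the other contrasts were set only against camera with an estimated correlation. Of 608 counts of higher or of lower genes, 104 moved by over 1.5 times. Signals near the floor limit the size of falls, and 246 dim genes were not tested.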

Other observations

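The 14 gene families, the tests of the array scaling, the array background and the weak-acid response below were chosen after the results were seen, and the tests of other groupings of the arrays and of dim signals before.

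All 4 measured genes of serine synthesis rose at 300 s, SER2 by 1.88 ± 0.14 (SE, n = 3 each), SER3 by 1.88 ± 0.21, SER1 by 0.76 and SER33 by 0.64 on the log2 scale. Their median lay 1.44 above all genes (limma's camera, adjusted p = 2.65e-05 over 42 tests, but adjusted p = 0.0852 with an estimated correlation). Of 15 tRNA modification genes 7 rose and 1 fell, with TRM5 up by 1.56 and TRM11 by 1.17 (camera adjusted p = 0.000865, and adjusted p = 0.152 with an estimated correlation). Of 18 cytosolic tRNA synthetases 5 rose, among them KRS1 by 1.05, with a camera adjusted p of 0.00267 (adjusted p = 0.0852 with an estimated correlation). Of 75 measured RPL and RPS genes of ribosomal proteins, 17 of them also in the single-copy list and many others with near-identical copies whose probe sets can bind both, 12 rose and the median lay 0.39 above all genes (camera adjusted p = 1.78e-08, and adjusted p = 0.246 with an estimated correlation), and 0.19 above with quantile normalization. At 120 s this family already lay 0.20 above all genes (camera adjusted p = 1.25e-10, and adjusted p = 0.215 with an estimated correlation). The tRNA synthetases lay 0.17 above at 120 s (camera adjusted p = 0.0199, and adjusted p = 0.131 with an estimated correlation). Serine synthesis and tRNA modification were not called at 120 s (camera adjusted p = 0.575 and 0.765).

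Of 56 mitochondrial ribosomal proteins 24 fell and 0 rose at 300 s, with MRP20 down by 1.70 ± 0.24 and MRPL28 by 0.90 on the log2 scale, and the family at -0.31 relative to all genes (limma's camera, adjusted p = 2.44e-05, but adjusted p = 0.231 with an estimated correlation). Of 34 autophagy genes 12 fell and 0 rose, among them ATG39 by 1.41 and ATG7 by 1.26 (camera adjusted p = 0.00331, and adjusted p = 0.168 with an estimated correlation). Of 34 proteasome genes 2 fell and 0 rose, and the family was not called (camera adjusted p = 0.615).

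Between 120 s and 300 s, 122 genes fell at least 2-fold, and 54.9% of them (67 of 122, exact 95% interval 45.7 to 63.9) had a 300 s mean over 4 times the floor, a split that the fall itself helps to set and that decides nothing about signals falling too far near background. For these 67 genes the fall, if it ran evenly, equals a halving every 147.5 s in the median, under 90 s for 7 of them and under 60 s for 1, TMA10, at 55.9 s (95% interval 50.8 to 62.3 s). Because only falls of at least 2-fold over 180 s were taken, no halving time can exceed 180 s, and this cut helps to set the median. TMA10 is the fastest of the 67, and its interval does not allow for that choice. On the single 210 s array, midway between these times, the 583 genes lower at 300 s had made a median 32.9% of their change. An even fall would give 50%, so halving in the later part may have been faster than stated here. Array scaling as the whole cause is argued against by ranks within each array on the deposited signals, which a factor per array leaves as they are, since of genes that fell at least 2-fold without the 120 s and 300 s arrays of 1 replicate number, 97.9% (140 of 143, exact 95% interval 94.0 to 99.6) ranked lower at 300 s on those held-out arrays, the lowest of 3 such shares, where scaling alone gives 50%. For the 67 genes, an array background subtracted too far would need at least 48 signal units more at 300 s, which puts genes under 60 at 120 s at the floor, and 18.4% of those (354 of 1923, exact 95% interval 16.7 to 20.2) lay at it on at least 1 of the 300 s arrays, well under the share of 80% it needs but with an upper limit just over the 20% set to exclude it. Of all tested genes, 2.74% to 4.55% lay at the floor on the 300 s arrays and 3.48% to 4.71% on the 120 s arrays. These values argue against such a background as the whole cause for the 67 genes, although the 20% mark was narrowly missed. For the other 55 genes, which ended near the floor, no value decides.

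AQR1 and TPO2, which led the increases at 300 s, are known to respond to weak acids, and one hypothesis is that acids formed after the pulse may act on the cells. Of 6 other weak-acid markers 2 rose, YRO2 by 0.82 ± 0.15 (limma adjusted p = 0.000912) and HRK1 by 0.56 ± 0.20 (limma adjusted p = 0.0427), and 0 fell by limma. This leaves the hypothesis open, since over 3 were needed and 3 of the 6 are also in the general stress list, of which 9 of 24 members fell.

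For the F test, 1 of 100 regroupings of the 15 arrays, the real one, gave 1921 genes and the highest other gave 1009. That other grouping placed 4 of the 5 late arrays in 2 groups of late arrays only, a structure close to the real one. The regroupings exchanged arrays freely across hybridization days, although pairs of arrays from the same day correlated at a median of 0.2. They therefore cannot exclude an effect of day that runs along with time. For 120 s, 300 s and 300 s against 120 s, 10 splits of the 6 arrays are too few for a share under 0.05. The real splits gave 4, 1648 and 1195 genes, each the 1 split with as many, and the highest other gave 0 in each.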
